A study of Mus musculus with 104 samples.

How the data were processed

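RNA was measured in E6.5 epiblasts and E8.5 heads of WT, Kmt2b KO and Tet1/2 DKO mouse embryos and in E9.5 heads of WT and Kmt2b KO embryos, and CpG methylation in Kmt2b KO epiblasts and in Kmt2b KO and WT heads. Per the labels' protocols, RNA libraries were made with Smart-seq2 and methylation libraries with STEM-seq, a bisulfite method for small samples, and heads were separated near the neck. Crosses were between DBA2 males and C57BL/6N females per the series design. Chromatin accessibility, histone mark and chromatin contact samples of the study were not analysed here.

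The RNA values deposited by the authors are FPKM, with TopHat2 (version 2.0.11) and Cufflinks (version 2.0.2) among the tools and mm9 as the build named in the submitters' processing notes. The Kmt2b table lists 22592 rows, of which 27 with names turned into dates were left out, and that of the Tet1/2 set 22593. For the Kmt2b set, 1 column per group merges the group's replicates. After sorting, its other 3 columns for E6.5 and E8.5 differ rank by rank from the WT epiblast column by at most 0.507% at 1 FPKM or more, and the 9 columns of the Tet1/2 table by at most 0.208% from its first, as quantile normalization would leave them. The E9.5 columns differ by up to 72.3% (WT) and 41.1% (KO) and were taken not to have been normalized with the others. Total FPKM per column was 451779 to 505676 in the first table and 459560 to 459595 in the second. FPKM give no read counts, so the depth and its precision are unknown. The 3 WT epiblast columns of the Tet1/2 table have no samples in that set and were taken to be the WT epiblasts of the Kmt2b set, whose merged column had r = 0.9995 with their mean over genes. The deposited Kmt2b table also has 2 columns of no listed sample, which were not used.

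For RNA, log2 of FPKM plus 1 was used, which makes differences of genes with low values smaller than their ratio. Genes with at least 1 FPKM in at least 2 columns of a fit were kept (11073 for the Kmt2b set, 10866 for the Tet1/2 heads, 11264 for the Tet1/2 epiblast and interaction), and small RNA genes were left out. Groups were taken from the sample labels. The plan for the Kmt2b set was a limma test over libraries, which could not be run with 1 merged column per group. Differences of at least 2-fold were counted instead, the spread between the WT libraries of the Tet1/2 table was set beside them, and no p-value was computed. The Tet1/2 set was fitted with limma 3.58.1 in R 4.3.3 (eBayes with a mean trend, Benjamini-Hochberg adjusted p under 0.05, two-sided). The fit for the heads held DKO epiblasts, WT heads and DKO heads, and the fit for the epiblast and for the interaction held these and the WT epiblasts. Of the target genes, Tet2 and Wbp7 were under the minimum in both fits.

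A total of 26 gene lists were fixed before the data were examined, together with the tests, the named genes and the alternative settings described below, apart from those said to be chosen later. In the Kmt2b set, the median of each list with at least 5 members was ranked among the medians of 10000 random lists matched on mean expression in 20 bins, and lists outside percentiles 2.5 to 97.5 are described. Lists in the Tet1/2 set were tested with camera (preset inter-gene correlation 0.01), with camera and an estimated correlation, and with fry. Hox genes had 4 members in the Kmt2b fit and were described one by one, and 0 mitochondrially encoded genes were listed.

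The genes named were, by rule, the 10 with the largest changes in each direction with at least 5 FPKM in the higher group and all libraries of one group above those of the other, the genes Kmt2b, Mll1, Tet1, Tet2, Tet3 and Magohb, and up to 4 members of each described list, except for a few genes not reported here. Without p-values, members of lists were ranked by the size of the difference in the Kmt2b set. Named after their values were seen were Wnt3 at E6.5, Lhx2, Fezf1 and the Hox genes in Kmt2b KO heads, Gstm5, Mt3, Nudt10, Bcap29 and 3110007F17Rik across stages, Dnmt3b, Tdgf1, Pou5f1 and T in the Tet1/2 DKO epiblast, the sex-linked genes, the genes shared by both mutants or both stages, and the imprinted genes.

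The methylation files deposited by the authors (unit other, whole-number read counts per CpG) have 1 row for each of 21342492 CpGs and pool the replicates of a group, per the labels. Trim Galore and BS-Seeker2 are named in the submitters' processing notes. The files have no header. That columns hold methylated and unmethylated reads of each strand was checked from the values, since levels of the strands had r = 0.789, 0.821 and 0.847 for the KO epiblast, KO head and WT head. Mean depth was 1.37, 1.97 and 2.12 reads per CpG, with 3.56%, 9.33% and 11.0% of CpGs at 5 or more reads, and the level over all reads was 67.8%, 67.6% and 68.2% (Wilson 95% intervals 67.826 to 67.8599, 67.6153 to 67.6436 and 68.1498 to 68.177). Reads carry no molecular identifiers, so intervals cover counting error only. CpGs with at least 5 reads in both pools were compared over the genome, by chromosome, in 10 kb bins and in CpG-dense regions, defined as merged windows of 500 bp with at least 25 CpGs, each with at least 10 shared CpGs. A difference of 20 points was counted. Promoter methylation, planned with gene positions on mm9, was not run because the gene annotation at hand is for another build, used here only for the order of genes.

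Each step was tested on simulated data. In the Kmt2b step 100 of 100 genes changed 4-fold and 0 of 100 changed 1.5-fold passed the 2-fold minimum, with 0 of 10834 unchanged genes. Between real WT libraries or columns 32 to 184 of 11073 genes passed it, so this simulation held less spread and its 0 is no error rate. For the Tet1/2 heads 20%, 50%, 76% and 90% of genes changed 1.5-, 2-, 4- and 8-fold were called, with 5 of 10472 unchanged genes, and in the epiblast 32%, 62%, 90% and 100%, with 7 of 10776. The genes changed in the Tet1/2 steps were drawn only from those above 5 FPKM in WT, so lower genes were not tested. Their noise was independent between genes, unlike that of real libraries. For methylation 77 of 78 regions simulated with a difference of 0.3, 5 of 71 with 0.15 and 1 of 10235 with 0 passed. Both pools were drawn around the WT levels with no spread between samples, so this 1 is no error rate either. Alternatives changed 1 choice at a time: pseudocounts of 0.1 and 5, no filter or at least 5 FPKM, small RNA genes kept, 3 scalings, robust eBayes, array weights, only the libraries of the comparison, each library left out, a block for the replicate number, a minimum log2 change of 1, and for methylation the read minimum, the bin size, the CpG density, the shared CpGs and the difference counted. Chosen after the data were seen were the Tet1/2 epiblast and interaction tests with all their alternatives, a fit of all 4 groups for the heads, sex-linked transcripts left out, the mean of E6.5 and E8.5 alone, the other WT heads for E8.5, reads summed per region (at least 50), and CpGs over 100 reads left out. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the rest.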

Results

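Mouse embryos lacking Kmt2b (KO), which encodes a histone H3 lysine 4 methyltransferase, and embryos lacking both Tet1 and Tet2 (DKO), which encode enzymes that oxidize 5-methylcytosine, were profiled around gastrulation and early head development. RNA of the E6.5 epiblast came from 3 WT, 3 Kmt2b KO and 2 Tet1/2 DKO samples. For the E8.5 head the Kmt2b set held 3 WT and 2 KO samples and the Tet1/2 set 2 WT and 2 DKO samples, and for the E9.5 head there were 3 WT samples and 1 KO sample. RNA levels were the authors' FPKM, whose read depth is unknown. The Kmt2b set had 1 merged column per group, so its differences are sizes with no error, no p-value and no replicate check. The Tet1/2 set had 1 column per library. Nothing in the labels says that replicates came from separate animals, so the p-values measure only the spread between these samples. DNA methylation was given as read counts per CpG, pooled over 3 E6.5 epiblast KO, 2 E8.5 head KO and 2 E8.5 head WT samples, with 29138288, 42047812 and 45262929 reads.

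Kmt2b itself, listed under its older symbol Wbp7, was lower in KO at every stage, although it stayed near the detection floor. Its merged values in WT and KO were 0.701 and 0.308 FPKM in the E6.5 epiblast, 0.600 and 0.133 in the E8.5 head, and 1.20 and 0.0349 in the E9.5 head. The related methyltransferase gene Mll1 (Kmt2a) had 1.41 FPKM in WT and 1.84 in KO at E6.5, 1.29 and 1.74 at E8.5, and 2.67 and 1.92 at E9.5. Tet1 was somewhat higher in KO, with log2 differences of 0.48, 0.28 and 0.52 at the 3 stages. Tet3, another 5-methylcytosine dioxygenase gene, had 1.86 and 1.60 FPKM at E6.5, 3.27 and 2.86 at E8.5, and 5.99 and 4.64 at E9.5. In the Tet1/2 set, Tet1 had 2.94 ± 0.55 FPKM in WT heads and 1.29 ± 0.01 in DKO heads (SD, n = 2 and 2, limma adjusted p = 0.157). In the epiblast it fell from 5.36 ± 0.82 to 3.37 ± 0.64 FPKM (n = 3 and 2, adjusted p = 0.0485), a call lost without any 1 of the epiblast WT libraries. Tet2 stayed under 1 FPKM throughout, at 0.430 and 0.488 in the WT heads and 0.251 and 0.383 in the DKO heads. A transcript with part of its exons deleted can still be counted, so these levels test the labels only weakly.

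The E6.5 epiblast comparison asked what loss of Kmt2b does to primed pluripotent cells as gastrulation begins. Primitive streak genes were lower in the KO epiblast and several pluripotency genes were higher. T, which encodes the mesoderm factor brachyury, had 14.8 FPKM in WT and 5.05 in KO (log2 difference −1.38). Mesp1, a gene of nascent cardiac mesoderm, had 20.9 and 7.93 FPKM (−1.29), and Mixl1, a homeobox gene of the streak, 138 and 67.3 FPKM (−1.02). Wnt3, a signal that starts streak formation, differed by −0.75, and Foxa2, a definitive endoderm factor, by −0.89. Of the 18 streak and mesoderm genes measured, 15 were lower, with a median of −0.42 at percentile 0 of 10000 random lists matched on expression. That median lies within the spread of the 3 WT epiblast libraries, whose own list medians had an SD of 0.67. By gene, their log2 SD was 0.62 for T, 1.09 for Mesp1, 1.11 for Mixl1 and 0.03 for Wnt3. Cyp26a1, a retinoic acid degrading enzyme of the streak, had 17.4 and 6.17 FPKM (−1.36, WT SD 1.01), and Cer1, an antagonist of Nodal and Wnt, 6.13 and 1.74 (−1.38, WT SD 2.08).

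Among the genes of formative and primed pluripotency, 16 of 23 were higher in the KO epiblast, with a median of 0.24 at percentile 99.9 of the random lists, close to the SD of 0.25 between the list medians of the WT libraries. The RNA-binding protein gene Lin28a had 22.8 FPKM in WT and 63.2 in KO (1.43, WT SD 0.30) and the pluripotency factor gene Pou5f1 245 and 451 (0.88, WT SD 0.12). Dppa4 differed by 0.82, within its WT SD of 1.24, and Pou3f1 by 0.81 (WT SD 0.27). The genes of H3K4 methyltransferases and demethylases lay slightly higher as a group, with 20 of 21 above 0 and a median of 0.24 (percentile 99.7). They included Psip1, a chromatin reader (0.60), and Cxxc1, a CpG island binding subunit (0.54). Ribosomal protein genes, whose reads can be shared with near-identical pseudogenes, were higher in 70 of 79 with a median of 0.26 (percentile 100). Naive pluripotency genes had a median of −0.37 (percentile 1.56) and hypoxia and glycolysis genes −0.19 (percentile 0.975, but 2.77 after quantile normalization, WT SD 0.24).

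In all, 188 of 11073 genes differed at least 2-fold between the merged E6.5 columns, 120 higher and 68 lower in KO. Among the largest differences with steady WT values were those of Anxa11, a calcium-dependent membrane-binding protein (3.44 to 19.4 FPKM, 2.20, WT SD 0.25), and Inppl1, an inositol phosphatase (1.64 to 9.28, 1.96, WT SD 0.29). On the lower side were Fmr1nb (41.9 to 10.7, −1.88, WT SD 0.18), Amd1, which encodes a polyamine synthesis enzyme (73.3 to 15.2, −2.20, WT SD 0.38), Bcap29 (6.58 to 1.64, −1.52, WT SD 0.41) and H2afy, the gene of the histone variant macroH2A (5.5 to 1.47, −1.40, WT SD 0.20). Sf3a2, a splicing factor gene, had a log2 difference of 2.59 with a WT SD of 0.96, and Amd2, a near-identical copy of Amd1, one of 2.80 with an SD of 2.82. The values of Hist2h3b (2.45), Hist2h3c2 (2.03), Hist1h2ak (2.16), Hist1h4c (1.96), 2610019E17Rik (2.13), Gm12669 (2.29) and Oaz1-ps (−4.09) are uncertain, since near-identical copies or overlapping transcripts share their reads. Single WT epiblast libraries set against the mean of the others gave 184, 170 and 140 such genes. Those set 1 library against 2, where the 188 set merges of 3 samples each, which average out more spread. How many of the 188 lie beyond the WT spread is therefore not known. The female transcript Xist was at 2.01 FPKM in KO against 0.0954 in WT and the Y-linked Ddx3y at 12.6 against 21.9, a difference in the sex of the pooled embryos. With a pseudocount of 5, 82.5% of the 40 genes that differed were higher, against 63.8% of the 188, and with 0.1 it was 52.5% of 589.

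**Figure D1:**
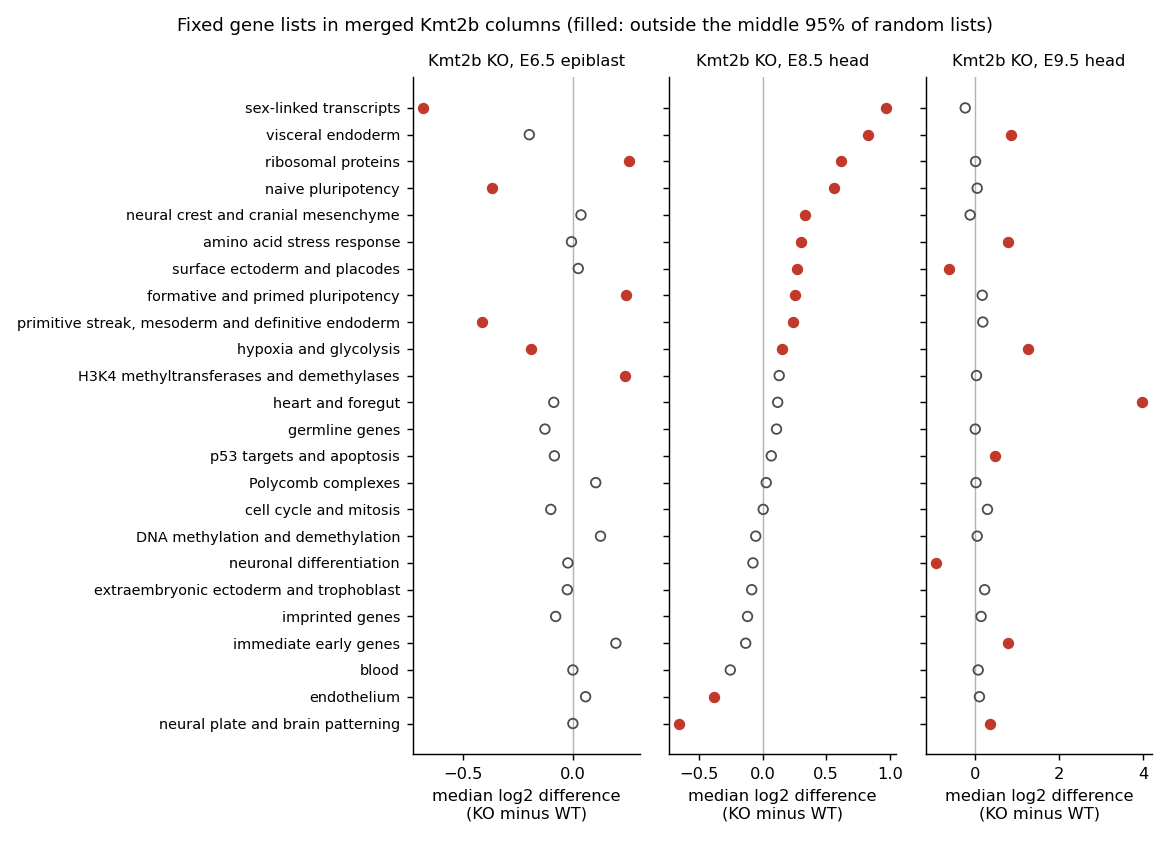
Median log2 difference (KO minus WT, of FPKM plus 1) of each fixed gene list in the merged Kmt2b columns, 1 point per list and stage, filled where the median lies outside the middle 95% of 10000 expression-matched random lists. Streak genes lie at −0.42 at E6.5, brain patterning genes at −0.65 at E8.5, and heart and foregut genes at 3.98 in the single E9.5 KO library.

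At E8.5 the question moved to the head, where genes of brain patterning were lower in KO and several Hox and early embryonic genes were higher. Of 23 genes of the neural plate and brain patterning, 9 were at least 2-fold lower and 2 higher, with a median of −0.65 (percentile 0). Genes of this list can move together, with an estimated inter-gene correlation of 0.47 in the Tet1/2 head fit. Random lists do not reproduce that, so the percentile does not measure the spread between samples. Pax6, an eye and forebrain regulator, had 19.5 FPKM in WT and 4.59 in KO (−1.88), Rax, required for eye formation, 7.77 and 1.56 (−1.78), and Otx1, a forebrain and midbrain homeobox gene, 22.8 and 6.58 (−1.65). Lhx2 and Fezf1, further forebrain regulators, differed by −1.65 and −1.57. The hindbrain gene Egr2 went the other way, with 0.513 and 5.38 FPKM (2.08). All 4 Hox genes listed at 1 FPKM or more in either column were higher in KO, such as Hoxb1 by 2.14 and Hoxb2 by 1.83. Hopx, a homeodomain-only gene of heart and stem cells (10.5 to 0.501, −2.94), and Aldh1a2, which encodes a retinoic acid synthesis enzyme (11.4 to 0.823, −2.76), were lower. Nptx2, a secreted neuronal pentraxin (0.572 to 16.3, 3.46), and the cytochrome gene Cyct (0.733 to 9.53, 2.60) were higher. The brain patterning list lay the other way in the single E9.5 KO library, with a median of 0.35.

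Several early embryonic genes were higher in the E8.5 KO heads. Lefty2, a Nodal antagonist, had 0.532 and 8.20 FPKM (2.59), Wnt8a, a posterior signal, 0.183 and 5.94 (2.55), and Nodal 0.209 and 2.11 (1.36). Pou5f1 had 3.91 and 16.9 FPKM (1.87), the pluripotency factor gene Nanog 1.59 and 8.27 (1.84), the amino acid transporter gene Slc7a3 3.63 and 16.6 (1.93) and Fgf5, a growth factor of the epiblast, 1.70 and 6.94 (1.55). The list medians were 0.25 for formative and primed pluripotency (5 of 23 at least 2-fold higher, percentile 99.7, with an SD of 0.28 between the other set's WT head libraries), 0.56 for naive pluripotency (percentile 99.1), 0.24 for the streak and mesoderm list (2 of 18 at least 2-fold higher, percentile 97.8, against such an SD of 0.23) and 0.83 for visceral endoderm (percentile 99.98). Epithelial genes followed, with Cdh1 at 3.01 and 15.3 FPKM (2.03) and Epcam at 26.7 and 80.6 (1.56) within a surface ectoderm and placode median of 0.27 (percentile 97.9). The neural crest list had a median of 0.33 (percentile 99.8), while 3 of its 20 genes were at least 2-fold lower, Tfap2b (2.86 to 0.20, −1.69), Sox10 (−1.61) and Ets1 (−1.18), and 0 at least 2-fold higher. Embryonic globins were lower, with Hba-x at 33.0 and 0.820 FPKM (−4.22), Hbb-bh1 at 45.9 and 2.45 (−3.76) and Hbb-y at 18.8 and 1.61 (−2.93), and endothelial genes had a median of −0.39 (percentile 1.05). Ribosomal protein genes had a median of 0.62 (percentile 100), with Rps18 at 63.2 and 230 FPKM (1.84).

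At least 2-fold differences at E8.5 were counted for 523 of 11073 genes, 245 higher and 278 lower in KO, against 32 between the merged WT column and the mean WT head of the Tet1/2 set and 133 between that set's 2 WT libraries. Set against those other WT heads, 439 of the 523 again differed at least 2-fold, 201 of the 245 and 238 of the 278. The same merged KO column enters both counts, so this tests the choice of WT heads and not the spread between KO samples. With pseudocounts of 0.1 and 5 the count was 1152 and 152. Snrpn, Snurf, Tpm3 and Hnrnpd are listed at 0 in the WT column and Eftud2 in the KO column, and since these genes are widely active, no fold was drawn from them. Zeros such as those of Tpm3 and Eftud2 were not left out of the counts. Ddx3y was at 7.12 FPKM in KO and 2.21 in WT, with Xist at 6.23 and 9.17.

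**Figure D2:**
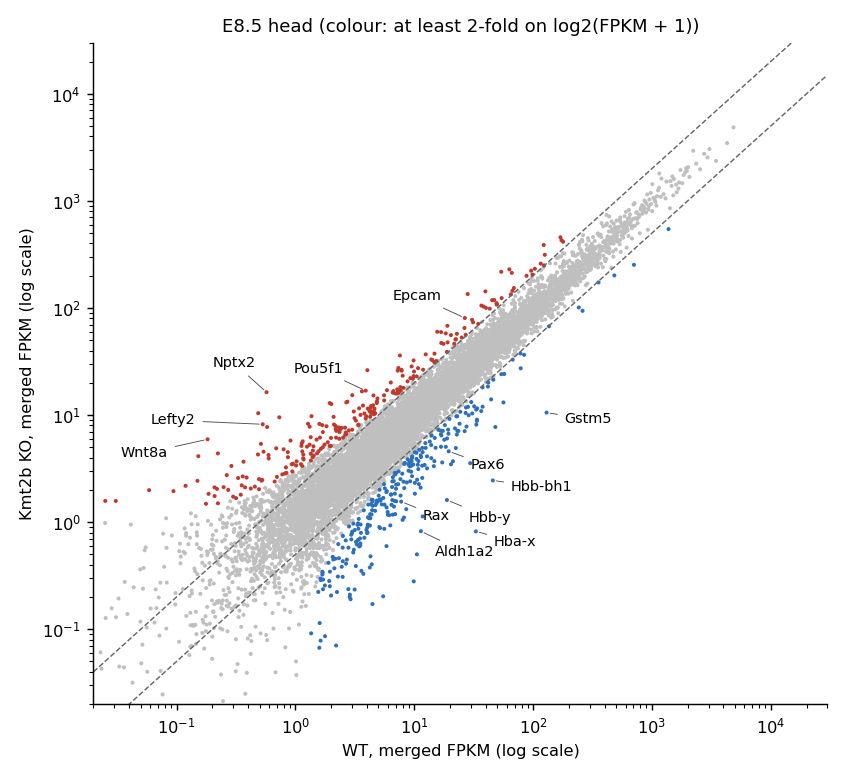
Merged FPKM of each gene in E8.5 Kmt2b KO heads (vertical) against WT heads (horizontal), both on log scales, with dashed lines at a 2-fold ratio. Lefty2, Wnt8a and Pou5f1 lie above the lines and Pax6, Rax and the embryonic globins below them.

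The E9.5 head comparison rests on a single KO library, whose column name carries another tissue code than its title, so whether it held only head tissue is in doubt. Heart muscle genes stood far above WT in it. The atrial light chain gene Myl7 had 10.8 FPKM in WT and 1080 in KO (6.51), Myl4, another atrial light chain gene, 0.218 and 351 (8.18), Tnni1, a troponin gene, 0.0591 and 121 (6.85), and the cardiac actin gene Actc1 9.73 and 790.4 (6.20). Tnnt2 (5.90), Tnnc1 (5.75), Csrp3 (5.88) and Acta2 (5.39), further genes of contractile tissue, were likewise higher, and Myl3 had 127 FPKM where WT is listed at 0. Of 10 heart and foregut genes 6 were at least 2-fold higher, with a median of 3.98 (percentile 100). Of 12 Hox genes at 1 FPKM or more in either column, 11 were higher in KO, among them Hoxa5 (2.92 FPKM, listed at 0 in WT), and Hoxa2 was lower (−0.35).

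Metabolic and stress genes were also higher in the E9.5 KO library. Hypoxia and glycolysis genes were at least 2-fold higher in 17 of 25 with a median of 1.25 (percentile 100), including the aldolase gene Aldoc (2.97 to 31.7 FPKM, 3.04) and the glucose transporter gene Slc2a1 (50.1 to 260, 2.35). Amino acid stress genes had a median of 0.79 with 7 of 16 at least 2-fold higher, such as Asns, which encodes asparagine synthetase (1.62), and Chac1, a glutathione-degrading enzyme gene (2.20). Immediate early genes had a median of 0.77, with Myc at 7.83 and 37.9 FPKM (2.14). Lower were neuronal genes (5 of 12 at least 2-fold, median −0.94), such as Elavl4, a neuronal RNA-binding protein gene (14.4 to 2.37, −2.19), and Tubb3, a neuronal tubulin gene (−1.38). Surface ectoderm and placode genes were lower too (4 of 13, median −0.62), such as Trp63, a regulator of stratified epithelium (−1.97). Aldh1a3, a retinoic acid synthesis enzyme of the eye (53.9 to 2.83, −3.84), Fabp7, a radial glia gene (244 to 21.6, −3.44), Crym (−3.19) and Sostdc1, a secreted BMP antagonist (−3.05), had the largest negative differences among genes above 0 in both columns, with Gstm5 at −2.85. In all 914 of 11073 genes differed at least 2-fold, 519 higher and 395 lower, or 69.4% of 324 higher with a pseudocount of 5. Xist and its antisense partner Tsix, at 8.08 and 26.8 FPKM in WT, are listed at 0 in the KO library, and of the Y-linked genes Ddx3y was at 9.34 against 3.20 FPKM and Uty at 1.98 against 1.27, but Eif2s3y at 6.44 against 7.78 and Kdm5d at 0 against 1.08.

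A small group of genes had lower values in the KO columns at every stage. Magohb, which encodes a core part of the exon junction complex, had 93.5 FPKM in WT and 40.5 in KO at E6.5 (−1.19, WT SD 0.07), and 63.9 and 64.2 FPKM in WT heads at E8.5 and E9.5, where both KO columns list it at 0. Since this file also lists widely active genes at 0, no fold was drawn from these zeros and whether the transcript is lost in KO heads stays open. Gstm5, a glutathione transferase gene, had 130 FPKM in WT and 10.6 in KO at E8.5 (−3.50) and 212 and 28.4 at E9.5. Bcap29, Mt3, Nudt10 and 3110007F17Rik were the other genes at least 2-fold lower at all 3 stages, 6 in all where independent columns would share 0.0609, and 0 genes were higher at all 3 stages. Of the 6, Magohb, Mt3 and 3110007F17Rik rest on zeros in both KO head columns, and the E6.5 difference of Mt3 (−1.06) is smaller than its WT SD of 1.41. Averaged over the stages, 142 genes differed at least 2-fold, 63 higher and 79 lower. Hmgn3, a nucleosome-binding protein gene, had a mean of −2.03 (16.1 to 8.35, 48.1 to 7.73 and 105 to 15.0 FPKM), Nxt2, an RNA export factor gene, −1.81, and Elovl2, a fatty acid elongase gene, −1.72. On the higher side Fgf15, a growth factor gene of the midbrain and hindbrain, had a mean of 1.67 (36.1 to 38.5, 39.7 to 143 and 5.97 to 58.5 FPKM). Without the doubted E9.5 library the mean of E6.5 and E8.5 gave 126 genes, 47 higher and 79 lower, of which 64 were among the 142. The genes lower at both E8.5 and E9.5 numbered 71 where independent lists would share 9.92, and those higher at both 42 where they would share 11.5. Across genes, the KO differences of the stages had Spearman correlations of 0.144 (E6.5 and E8.5), 0.144 and 0.101, and genes are not independent replicates.

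Between E6.5 and E8.5 the KO difference itself shifted for many developmental genes. Cyp26a1 moved by 3.47, Wnt8a by 3.42, Cfc1, a Nodal co-receptor gene, by 3.39, Nptx2 by 3.45 and Coch by 3.57, all relatively higher in KO at E8.5. The histone genes Hist2h3b (−4.27), Hist1h2ak (−4.02) and Hist1h4c (−3.75), whose copies share reads, moved the other way. Of 18 streak and mesoderm genes 9 moved up by at least 2-fold (median 0.85, percentile 100), and of 23 brain patterning genes 9 moved down (median −0.73, percentile 0). In all 787 genes moved at least 2-fold, 403 up and 384 down. No test of this difference was possible with merged columns, and the stage and the tissue changed together.

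In WT heads, E9.5 against E8.5 gave the normal course of the tissue. Embryonic globins were far higher at E9.5, with Hbb-y at 18.8 and 7391 FPKM (8.54), Hbb-bh1 at 45.9 and 5392 (6.85) and Hba-x at 33.0 and 2979 (6.45). Aldh1a3 (0.885 to 53.9, 4.86) and Fabp7 (14.9 to 244, 3.94) were higher, as were neural crest and mesenchyme genes (11 of 20 at least 2-fold higher, median 1.08) such as Col3a1, a collagen gene (3.26), and Twist1, a mesenchymal regulator (2.12). Eras (42.9 to 0.904, −4.53), a Ras gene of early embryonic cells, Hes3 (37.6 to 0.607, −4.59), a neural progenitor repressor, Foxh1, a Nodal pathway factor (20.4 to 0.170, −4.19), and Hmga1, a chromatin protein gene (81.2 to 3.41, −4.22), were lower. Heart and foregut genes were at least 2-fold lower in 6 of 10 (median −1.74), such as Myl4 (16.3 to 0.218, −3.83), and hypoxia and glycolysis genes in 9 of 25 (median −0.57). Heart genes were very uneven between the WT E8.5 heads of the Tet1/2 set, as given below, so the size of their difference is uncertain. Differences of at least 2-fold were counted for 2113 genes, 970 higher and 1143 lower. The E9.5 columns were not normalized with the others, and scaling to equal totals moved the median of all genes by −0.15 and the split to 772 higher and 1379 lower.

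In E8.5 heads lacking Tet1 and Tet2, the question was what loss of these dioxygenases does to the early head. Of the 47 genes called, some with large changes are named here. Hdac1, which encodes a histone deacetylase, rose from 8.58 ± 0.29 to 52.6 ± 4.65 FPKM (SD, n = 2 and 2, log2 2.48, limma adjusted p = 0.0044), and Hmgn2, a nucleosome-binding protein gene, from 191 ± 4.98 to 864 ± 15.7 (2.17, adjusted p = 0.00039). Hist1h2af rose from 15.8 ± 3.12 to 406 ± 92.7 (4.59, adjusted p = 0.0044) while Hist1h2ag fell from 714 ± 111 to 90.6 ± 1.66 (−2.96, adjusted p = 0.0018). Hist1h2ad, Hist1h2an and Hist1h2ah rose by 1.93 to 2.12 and Hist1h4i fell by 2.03, and reads shared between histone copies make each of these values uncertain. Fggy, a carbohydrate kinase gene (0.240 ± 0.034 to 9.66 ± 0.10, 3.10), and Ube2t, a ubiquitin-conjugating enzyme of DNA repair (7.15 ± 1.94 to 30.4 ± 6.57, 1.95), rose too. Pttg1, the gene of securin, fell from 293 ± 6.44 to 51.7 ± 5.29 (−2.48, adjusted p = 0.0018), Rbm45, an RNA-binding protein gene, from 35.9 ± 0.40 to 5.5 ± 1.69 (−2.53), and Csrp1, a smooth muscle LIM protein gene, from 21.9 ± 0.60 to 1.84 ± 0.12 (−3.01). Cap1, an actin regulator gene, fell by 2.15, Thg1l, a transfer RNA guanylyltransferase gene, by 2.06 and Mtfr2, a mitochondrial fission regulator gene, by 2.15.

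Few gene lists were called in the DKO heads, and none with every method. Camera with a preset correlation called 4 of 23 lists lower at an adjusted p of 0.0487: formative pluripotency (median −0.21), heart and foregut (−2.15), DNA methylation and demethylation (−0.32) and hypoxia and glycolysis (−0.25). With the correlation estimated camera called 0 lists, 0 also at an unadjusted p under 0.05, and these 4 had adjusted p = 0.815 to 0.834 with an estimated correlation. Fry called 0 lists, with 4 at an unadjusted p under 0.05. None of their genes passed over all genes tested, and when adjusted over the list alone 0 higher and 4 lower heart genes, 0 higher and 5 lower DNA methylation genes, with the deleted Tet1 (−0.78) first among them, 1 higher and 3 lower hypoxia genes and 0 formative genes passed. The heart genes had very uneven WT libraries, with Myl7 at 58.9 ± 62.9 FPKM in WT and 2.16 ± 1.39 in DKO. Outside these lists, the apoptosis gene Bax fell by 0.84 (adjusted p = 0.023), and the ribosomal protein gene Rpl29 rose by 0.79. Magohb was at 58.9 FPKM in WT and 66.7 in DKO (adjusted p = 0.570).

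In total 47 of 10866 genes passed limma at an adjusted p under 0.05 in the heads, 28 higher and 19 lower, with 1830 at an unadjusted p under 0.05. Without WT head replicate 1 or 2 it was 7 or 10 genes and without DKO head replicate 1 or 2 it was 3 or 8, of those named here only Hmgn2, Pttg1 and Hist1h2ag in every case. Without epiblast DKO replicate 1 or 2, which enter the estimate of spread, 295 or 246 genes passed, and with all 4 groups of the table in the fit 160. The split turned with array weights (221 higher and 302 lower) and with all 4 groups in the fit (76 and 84). Both WT heads were Xist-high (7.80 and 9.05 FPKM) and both DKO heads were not (0.0116 and 0.0126), so sex and genotype cannot be told apart here. Tsix fell from 6.52 ± 3.54 to 0.0189 FPKM with them. Gm13157 (2.94), Gm13251 (1.85) and Rps3a1 (−2.16) passed as well, with reads that near-identical copies can share. Some calls also differed at least 2-fold the same way in Kmt2b KO heads. On the higher side these were 10 of 28, where independent lists would share 0.567, among them Hdac1, Fggy, Ube2t and Hist1h2af. On the lower side they were 5 of 18 measured in both (0.474), among them Csrp1, Pttg1, Hist1h2ag and Hist1h4i. These changes are thus not shown to be particular to Tet1/2 loss.

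**Figure D3:**
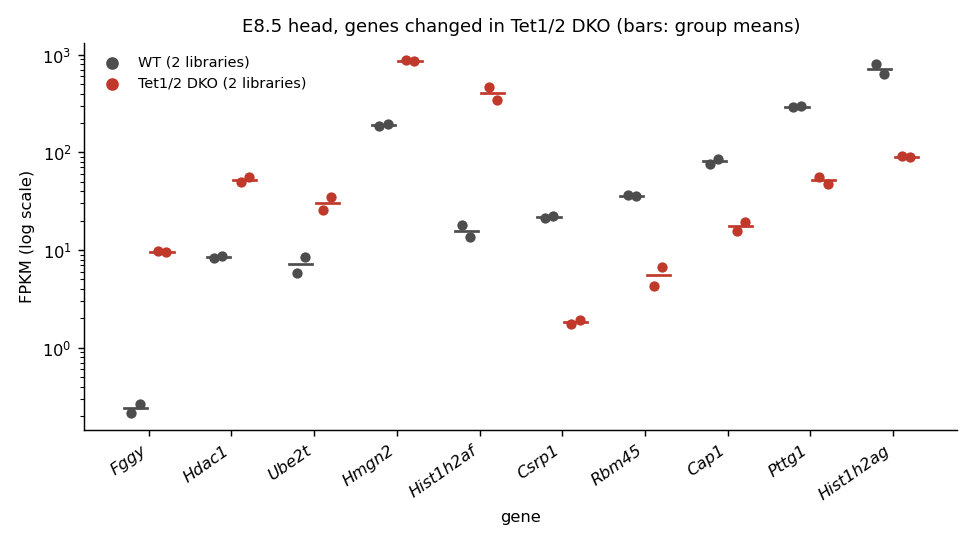
FPKM (log scale) of named genes in each E8.5 head library of the Tet1/2 set, 1 point per library, with bars at the group means. Hdac1 lies at 8.58 in WT and 52.6 in DKO on average, and Pttg1 at 293 and 51.7. Several of these genes, Hdac1 and Pttg1 among them, also differed at least 2-fold the same way in Kmt2b KO heads.

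In the E6.5 epiblast lacking Tet1 and Tet2, many streak genes fell. Mixl1 fell from 155 ± 93.5 to 1.55 ± 0.46 FPKM (SD, n = 3 and 2, −5.71, limma adjusted p = 0.00036), Mesp1 from 23.4 ± 13.8 to 0.15 ± 0.21 (−4.19, adjusted p = 0.00091) and Cyp26a1 from 18.998 ± 13.1 to 0.192 ± 0.12 (−3.85). Wnt3 fell from 6.27 ± 0.16 to 0.266 ± 0.22 (−2.53, adjusted p = 0.00013), Nodal from 26.4 ± 1.16 to 5.82 ± 1.73 (−2.03), Fgf8 from 56.7 ± 8.98 to 8.31 ± 1.49 (−2.63) and T by 2.42. Fst, a secreted activin antagonist gene, fell from 41.8 ± 11.9 to 3.19 ± 1.01 (−3.33) and the adaptor protein gene Ap1s3 from 22.2 ± 2.38 to 1.08 ± 0.61 (−3.51). Of the 21 streak and mesoderm genes tested, 12 fell and 0 rose over all genes, and 13 fell when adjusted over the list alone (median −1.50). Camera with the preset correlation gave adjusted p = 3.25e-07 for this list, lost at adjusted p = 0.593 with an estimated correlation, and fry, which tests whether a list's genes move on balance, gave 0.0043.

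Several pluripotency genes rose in the same epiblasts, where 11 of 23 genes of formative and primed pluripotency rose and 1 fell (13 and 1 adjusted over the list alone, median 0.56). This list had a preset-correlation adjusted p of 0.0276, with adjusted p = 0.593 with an estimated correlation. Lin28a rose from 23.1 ± 4.73 to 59.9 ± 8.80 FPKM (1.35), the Wnt effector gene Lef1 by 1.30, the Fgf target gene Etv5 by 1.19, Utf1, a chromatin gene of pluripotent cells, by 1.10 and the methyltransferase gene Dnmt3b by 0.94, while Tdgf1, a Nodal co-receptor gene, fell by 1.54. Pou5f1 had 242 ± 21.1 and 442 ± 23.3 FPKM (adjusted p = 0.0662). Among H3K4 enzymes 10 of 21 rose and 0 fell (14 and 0 adjusted over the list alone, median 0.47), including Ncoa6 (0.99) and Men1 (0.68), subunits of H3K4 methyltransferase complexes, with adjusted p = 0.000704 at the preset and 0.593 with an estimated correlation. Ribosomal protein genes fell in 57 of 79 and rose in 8 (60 and 8 adjusted over the list alone, median −0.86), with adjusted p = 2.05e-17 at the preset and adjusted p = 0.593 with an estimated correlation. Rpl19 fell from 462 ± 20.5 to 82.0 ± 5.08 FPKM (−2.48, adjusted p = 3.1e-06), and pseudogene copies can take such reads. Polycomb genes rose in 9 of 25 and fell in 2, among them Cbx2 (1.86) and Kdm2b (1.41), and DNA methylation genes rose in 7 of 15 and fell in 1, with Dnmt1 up by 0.87 and Uhrf1, its cofactor, by 0.71. Both lists missed the threshold with camera (adjusted p = 0.0843) and passed fry (0.0037 and 0.0078). The list counts stand against 2260 of all 11264 genes that rose and 1710 that fell. Fry does not set a list against the other genes, and 16 of 23 lists had an unadjusted p under 0.05 by fry.

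Among the largest changes outside these lists, Sf3a2 rose from 3.09 ± 2.95 to 82.9 ± 7.69 FPKM (4.58), Msi1, a neural RNA-binding protein gene, from 0.591 ± 0.32 to 12.9 ± 1.05 (3.15), Lars2, a mitochondrial leucyl-tRNA synthetase gene, from 47.1 ± 19.3 to 370 ± 6.38 (3.03), and Tesc, a calcium-binding protein gene, from 1.69 to 14.1 (2.63). Spink3, a protease inhibitor gene, was at 7.78 ± 6.55 FPKM where all 3 WT libraries list 0. The values of Hist2h3b (3.81), Hist1h2ak (2.92), Hist2h3c2 (2.74), Rps29 (−3.19), Rps28 (listed at 0 in DKO), Oaz1-ps (−5.58), Gm15772 (−5.12) and Gm6548 are uncertain for shared reads. Magohb fell from 96.8 to 60.4 FPKM (−0.67, adjusted p = 0.0048). Altogether 3970 of 11264 genes passed, 2260 higher and 1710 lower, and 2499 without DKO epiblast replicate 2. With a log2 change of at least 1 the split turned, with 528 higher and 735 lower. The WT epiblasts came from the Kmt2b set, so any difference between the sets adds to that between the genotypes and cannot be told apart from it. All 3 WT epiblasts were Y-high, and of the DKO epiblasts 1 was Y-high (Ddx3y 15.5 FPKM) and 1 was not (0.0746).

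**Figure D4:**
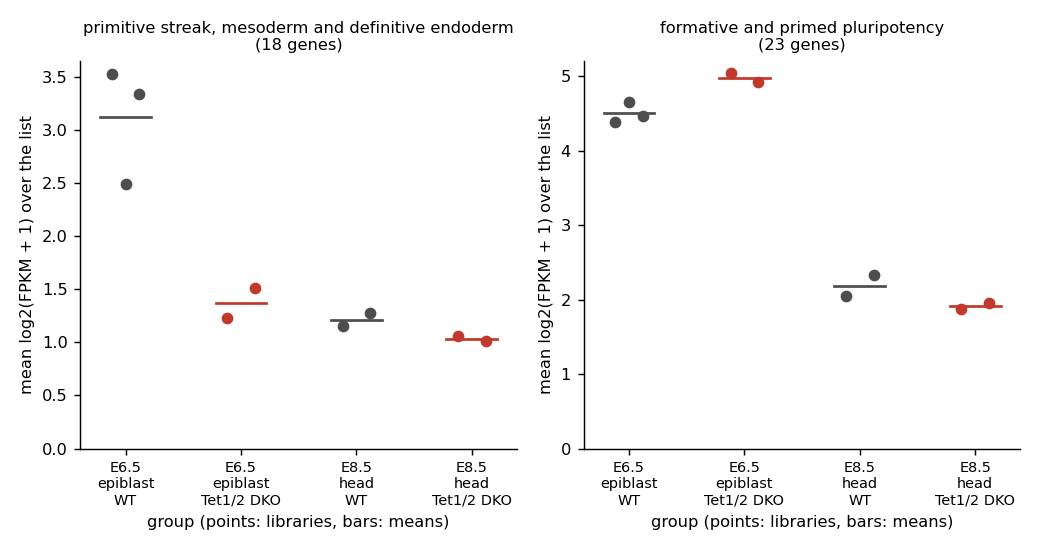
Mean log2 of FPKM plus 1 over the primitive streak, mesoderm and definitive endoderm list (left) and the formative and primed pluripotency list (right) in each library of the Tet1/2 table, 1 point per library with bars at group means. For the streak list the 3 WT epiblast libraries lie between 2.49 and 3.52 and the DKO epiblast libraries at 1.23 and 1.51.

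The effect of Tet1/2 loss differed between the epiblast and the head for many of these genes. The effect on Mixl1 was 5.71 higher in the head (limma interaction, adjusted p = 0.0025), where its FPKM was near 0 in both genotypes, and that on Wnt3 was 2.44 higher. For Hdac1, which rose in the head and fell by 0.62 in the epiblast, the effects differed by 3.10 (adjusted p = 0.00018), and for Rpl19 by 2.58 (adjusted p = 6.0e-05). Lin28a, which rose in the epiblast, had an effect lower by 2.06 in the head, and Lef1 one lower by 1.65. Interaction passed for 2976 of 11264 genes, 1225 with the higher effect in the head and 1751 with the lower, and for 1604, 1671, 1161 and 1640 without WT head replicates 1 and 2 and DKO head replicates 1 and 2. Of the lists, 10 of 21 streak genes passed upward and 0 downward, 9 of 23 formative genes and 7 of 21 H3K4 genes passed downward with 0 upward, 5 of 15 DNA methylation genes passed downward with 0 upward, and 42 of 79 ribosomal protein genes passed upward with 4 downward. These 5 lists passed camera at the preset correlation, and each had adjusted p = 0.506 with an estimated correlation. Calls shared by both stages numbered 12 on the lower side where independent lists would share 2.82 (Fisher's exact test, two-sided, p = 2.0e-06) and 10 on the higher side where they would share 5.82 (p = 0.0615). The first group included Pttg1, Rbm45, Cap1, Mtfr2 and Hist1h2ag, the second Hmgn2 and 5 Hist1h2a genes, and both fits draw on the DKO epiblast and head libraries for their estimate of spread, so the 2 sets of calls are not independent.

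Kmt2b KO and Tet1/2 DKO heads at E8.5, each against its own WT set, had weakly related differences. Across 10525 genes, which are not independent replicates, Spearman's rho was 0.165 and Pearson's r 0.125, and rho was 0.0976 without WT head replicate 1 of the Tet1/2 set. Genes at least 2-fold higher in both numbered 28 where independent lists would share 2.85, including Nptx2 and Hdac1, and genes lower in both 30 where they would share 3.45, including Hopx, Pttg1 and Csrp1. Without histone genes, whose copies share reads, and sex-linked genes these were 25 and 17. Opposite directions were found for 13 genes higher in KO and lower in DKO (2.65 for independent lists), including Pou5f1, Utf1 and Foxh1, and for 14 genes lower in KO and higher in DKO (3.71), including Hba-x, Hbb-bh1 and Ets1. The 13 also hold Tpm3 and the 14 Eftud2, genes from whose zeros no fold was drawn above.

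At E6.5 both mutants were set against the same WT embryos, so their differences share chance values. Streak genes were lower in both, and the mean product of the log2 differences over 18 streak genes was 1.26. Unchanged groups simulated against those WT libraries gave a mean of 0.103 and a highest value of 0.492 with genes drawn independently, but a highest of 1.31 with genes moving together, above the value seen. Genes at least 2-fold higher in both numbered 55, including Sf3a2, Hist2h3b and Lin28a, and genes lower in both 28, including T, Mesp1, Mixl1 and Cyp26a1, with no expected number computed for shared controls. Across 10758 genes Pearson's r was 0.41 against a simulated 0.447, and the covariance 0.103 against a simulated 0.0289. The shared WT libraries were not split between the mutants, so how much of the likeness comes from them stays open.

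The CpGs compared in the E8.5 head had nearly the same mean methylation in KO and WT, while single CpG-dense regions differed, mostly toward higher methylation in KO. Over 667742 CpGs with at least 5 reads in both pools the level was 36.4% in KO and 36.4% in WT, a difference of 0.0204 points. With at least 3 reads it was −0.129 points and with at least 10 reads 0.144. These CpGs are a part of the 21342492 listed, selected by depth. Over all reads of each pool the level was 67.6% in KO and 68.2% in WT, so level and difference depend on the CpGs counted. Among 10384 CpG-dense regions, 116 differed by at least 20 points, 106 higher and 10 lower in KO, and 391 passed Fisher's exact test at an adjusted p under 0.05, which compares these 2 pools and not the conditions. A wider set of 18676 regions, with at least 50 summed reads in every pool, was classed by the level over those reads. Of these, regions at 50% or more in KO alone numbered 157 and in WT alone 40, beside 3695 in both. Among 10 kb bins 109 were higher and 41 lower by at least 20 points, but with CpGs of at least 3 reads 659 of 1432 such bins were higher, so the split of the bins depends on coverage.

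Most of the largest regional differences shrank when more CpGs were used. In the mm9 build, the region on chromosome 11 from 29724515 to 29725538 was at 67.3% in KO and 24.2% in WT, or 43.0 points, against 49.4 with CpGs of at least 3 reads and 47.6 from all reads summed, the order used below. That on chromosome 6 from 8678825 to 8679313 was at 66.7% and 20.6% (46.1 points, then 43.4 and 34.5). Chromosome 4 from 146561213 to 146562380 was higher by 46.2 points (46.9 and 29.1), chromosome 7 from 6140785 to 6141714 by 46.9 (21.4 and 21.8) and chromosome 2 from 174120527 to 174122046 by 46.7 (27.2 and 20.2). On the lower side, chromosome X from 7722060 to 7723334 was at 2.86% in KO and 27.6% in WT (−24.8 points, then −30.6 and −21.7). Chromosome 7 from 6681953 to 6683467 differed by −45.9 points (−26.0 and −17.6) and chromosome X from 7498904 to 7500588 by −33.6 (−15.8 and −17.0). Chromosome 10 from 80933318 to 80933890, at −27.5 points, turned with at least 3 reads (1.72 and −11.6), and chromosome X from 147481064 to 147482712, at −24.5, from summed reads (−10.1 and 0.401). Whether positions count from 0 or 1 is not given, and genes near these regions were not named because the gene annotation at hand uses another build. The sex of the embryos in each methylation pool is unknown, which bears on the X-linked regions.

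**Figure D5:**
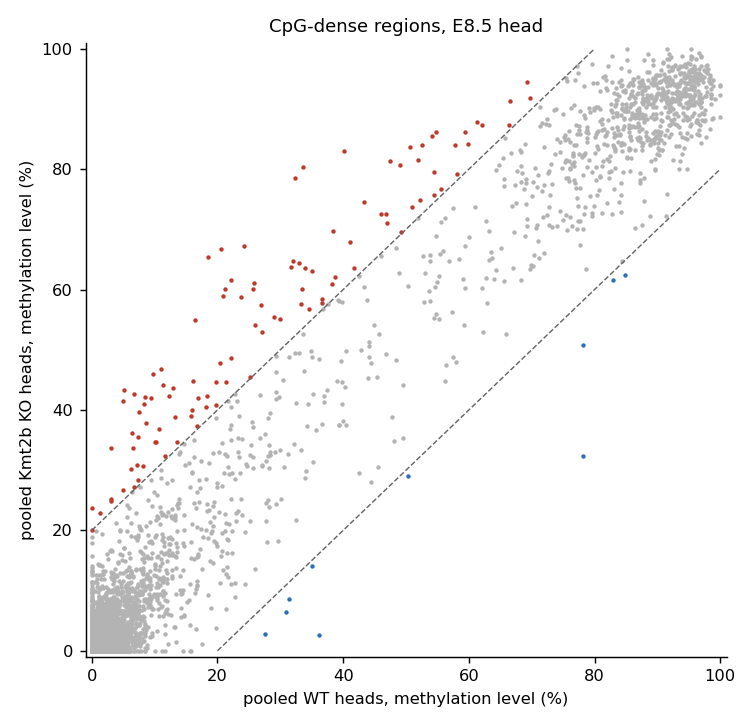
Methylation level (%) of 10384 CpG-dense regions in the pooled E8.5 Kmt2b KO heads (vertical) against the pooled WT heads (horizontal), 1 point per region, with dashed lines at a difference of 20 points. Above the upper line lie 106 regions and below the lower line 10.

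Between the KO epiblast and the KO head, shared CpGs were 0.627 points lower in the head (40.4% against 41.0% over 185640 CpGs), a sign that turned with a minimum of 3 reads (1.30 points). Of 3278 CpG-dense regions 98 differed by at least 20 points, 29 higher and 69 lower in the head, and of 4158 bins of 10 kb 49 were higher and 84 lower, which turned to 1788 higher of 2572 with the lower minimum. In the wider set of 18676 regions with at least 50 summed reads in every pool, the level over those reads was used again. Regions at 50% or more in the KO head alone numbered 194 and in the KO epiblast alone 131, beside 3658 in both. By chromosome the mean difference ran from −1.61 points (chromosome 3) to 0.488 (chromosome X). Only 3.56% of CpGs had 5 or more reads in the epiblast pool, and no WT epiblast pool was used here, so the difference is not shown to depend on Kmt2b.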

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

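Of the tests in this part, the interaction between stage and Tet1/2 loss, the Hox gene share in the E9.5 library, the E8.5 median of the heart list and the simulation with genes moving together were chosen only after the results they bear on were seen.

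Many genes differed between the stages in their response to loss of Tet1 and Tet2, among them 10 of 21 streak genes, which fell in the epiblast. In the heads Mixl1, Mesp1, Wnt3 and Nodal were under 1 FPKM in both genotypes. A total of 2976 genes passed limma's interaction test, among them those named here, given as the log2 effect in the head minus that in the epiblast. Values were 5.71 for Mixl1, 4.16 for Mesp1, 4.10 for Cyp26a1, 3.0 for Fgf8, 2.92 for Fst, 2.44 for Wnt3, 2.08 for T, 2.04 for Nodal and 3.54 for Ap1s3. Genes that rose in the head and had the higher effect there were Hdac1 (3.10), Fggy (2.54), Ube2t (1.69) and Hmgn2 (1.59). Magohb (0.86) fell in the epiblast and was not called in the head. Of 79 ribosomal protein genes 42 passed upward, with 2.58 for Rpl19, 0.44 for Rpl29, 4.67 for Rps28 and 3.20 for Rps29. Reads shared with near-identical copies make these values uncertain, and Rps28 was listed at 0 in the DKO epiblasts.

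Of 23 formative pluripotency genes 9 and of 15 DNA methylation genes 5 had the lower effect in the head, and the camera calls of both lists were lost with an estimated correlation (adjusted p = 0.506). By gene the values were −1.95 for Pou5f1, −2.06 for Lin28a, −2.12 for Utf1, −1.65 for Lef1, −1.22 for Etv5, −1.47 for Dnmt3b, −1.37 for Dnmt1 and −1.07 for Uhrf1. The chromatin genes Cbx2 (−2.16), Kdm2b (−1.69) and Men1 (−0.96), the apoptosis gene Bbc3 (−1.60) and the replication gene Mcm2 (−1.19) did so too. Further values were −4.89 for Sf3a2, −3.67 for Msi1, −3.35 for Lars2, −3.03 for Tesc, −3.67 for Spink3, −3.77 for Myl7, −3.16 for Csrp1, −1.70 for Pttg1, −1.63 for Cap1, −1.06 for Rbm45 and −1.69 for Thg1l. The sex-linked Ddx3y (6.41) and Tsix (−2.61) differ with the sex of the embryos. Copies that share reads gave 2.53 (Hist1h2af), −2.16 (Hist1h2ag), −3.96 (Hist1h2ak), −0.97 (Hist1h4i), −5.20 (Hist2h3b), −4.06 (Hist2h3c2), 3.73 (Gm13157), 1.62 (Gm13251), 3.45 (Gm6548) and 5.59 (Oaz1-ps). The WT epiblasts came from the other set, so a difference between sets adds to each value and cannot be told apart from it.

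Primitive streak genes were lower in both E6.5 knockouts. For Tet1/2 DKO, 1 WT library richer in streak tissue is argued against, since the lowest WT library lay above the highest DKO library by 0.983 on the mean log2 scale, more than the WT SD of 0.549. Chance values of the shared WT libraries stay open, with a mean product of both sets of differences of 1.26 over the list. This lies above the highest of 1000 simulations with genes drawn independently (0.492), the bound set beforehand, but that bound was too narrow because streak genes move together among WT libraries, and with genes moving together the highest was 1.31. For Kmt2b KO no library values were at hand, and neither a role of the genes in streak formation nor a difference in embryo age was tested.

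Heart muscle genes were far above WT in the single E9.5 Kmt2b KO library. The authors' normalization of the E9.5 columns is argued against, because the heart list kept a median of 4.0 after quantile normalization of all columns together. Tissue from below the head may have entered this library, since 91.7% of 12 Hox genes were higher in it, where under 50% would have spoken against it. Loss of Kmt2b raising heart genes in the head stays open as well, for the E8.5 KO heads had a heart list median of 0.12, too small to meet its prediction and too large to exclude it at another stage. With 1 KO library these explanations cannot be told apart.

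Histone genes were 7 of the 47 calls in Tet1/2 DKO heads, 5 higher and 2 lower. If reads had only moved between near-identical copies, the summed Hist1h2a FPKM would have stayed level, but it differed by 0.92 on the log2 scale, with the lowest DKO library 0.685 above the highest WT library. That gap is under the 1 set in advance to exclude such moves, so they stay open, and the other families summed lower in DKO (−0.71, −0.60, −0.43, −0.84 and −0.71 for Hist1h2b, Hist1h3, Hist1h4, Hist1h1 and Hist2). Sex also stays open, because both WT heads were Xist-high and both DKO heads Y-high. The genes that rose had a median of −0.0387 in the Y-high minus the Y-low DKO epiblast, and 1 library of each sex excludes nothing. No biological explanation was tested.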

How the results depend on the processing

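Of the alternatives in this part, all those of the Tet1/2 epiblast and interaction results, the fit of all 4 groups, the left-out sex-linked transcripts and deep CpGs, the mean of E6.5 and E8.5 alone and the reads summed per region were chosen only after the data were seen. Named genes of the Kmt2b set that differed at least 2-fold kept their direction in every setting tried, and for smaller differences direction was not checked. By construction, filters leave a gene's value unchanged, and pseudocounts cannot turn the difference between a KO and a WT column. Pseudocounts could turn the mean over stages and the change between stages. The scalings change little in the E6.5 and E8.5 columns, which were already alike in their sorted values. For the Tet1/2 heads the counts depended strongly on single libraries. Merged columns and pooled methylation reads carry no replicate error, the depth of the FPKM is unknown, and the low coverage of the methylation pools limits every regional count. In the Kmt2b set no paired analysis was possible because its merged columns carry no replicate numbers, and a fit that takes the 3 stages as replicates was not run. Not run for that set for the same reason were robust eBayes, array weights, only the libraries of the comparison, each library left out, the replicate block, the minimum log2 change with an adjusted p, camera, fry and other splits of the samples, and promoter methylation was not run for lack of gene positions on mm9. Fisher's exact test between the mutants was replaced by counts.

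The counts of genes at least 2-fold different in the Kmt2b set moved with the pseudocount, which by construction sets how much low genes count. With 0.1 they were 589 at E6.5, 1152 at E8.5, 1708 at E9.5, 477 for the mean and 1563 for the change between stages, and with 5 they were 40, 152, 324, 30 and 248, with 884 for WT E9.5 against E8.5. A minimum of 5 FPKM, which tests fewer genes, gave 113, 591, 89 and 509 at E6.5, at E9.5, for the mean and for the change. The other settings kept each count within 1.5 times. Of 397 values of 51 named genes at E8.5 82 moved by at least the WT spread or had no spread to be set against. Of these, 29 came with a pseudocount of 0.1 and 38 with 5. So did 73 of 292 values move at E9.5 and 23 of 279 at E6.5. For the mean it was 16 of 78, for the change 11 of 62 and for the WT heads 32 of 94. Filters and small RNA genes kept leave a gene's value unchanged by construction. Reversals, counted only for differences of at least 2-fold, numbered 0. After quantile normalization 13 of 48 list medians with an E9.5 column moved, and 4 of 72 without one, whose columns were already alike in their sorted values, so that the setting tests little there.

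In the Tet1/2 heads 47 genes were called, against 28 with no filter, 523 with array weights (42.3% higher, where 59.6% were), 284 with only the head libraries and 160 with all 4 groups in the fit (47.5% higher). The cause of these was not tested. Leaving out single libraries gave 3 (DKO head replicate 1) to 295 (DKO epiblast replicate 1), with 7 and 10 without WT head replicates 1 and 2, 8 without DKO head replicate 2 and 246 without DKO epiblast replicate 2. Fewer samples enter these fits, and where 1 library is left in an arm it is assumed to vary like the other groups. With the replicate number as a block 18 genes were called in the heads, 2802 in the epiblast and 1867 for the interaction, but the numbers do not pair the samples, with correlations of 0.0586, 0.102 and 0.0341 within numbers. Of 521 values of 25 named genes 431 kept their call, 87 lost it, 2 gained one and 1 reversed, Magohb without WT head replicate 1 (−0.0081), whose effect ran to 0.39 without WT head replicate 2. Quantile normalization, equal totals, small RNA genes kept and sex-linked transcripts left out changed none of the 25 and test little here. Most of the lost calls came with a head library left out.

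Tet1/2 loss in the epiblast gave 3970 genes, against 2421 with array weights and 2563 with only the epiblast libraries, for causes not tested, and 1263 with a log2 change of at least 1, a stricter minimum by construction. Leave-outs ran from 2499 (DKO epiblast replicate 2) to 4363. Of 961 values of 42 named genes 932 kept their call, 23 lost it and 6 gained one, and 0 reversed. The interaction's 2976 became 1702 with the minimum change and 1161 (without DKO head replicate 1) to 4053 with single libraries left out, with 1604, 1671 and 1640 without the other head libraries. Spearman's rho of both mutants' E8.5 effects was 0.165, and 0.0976 (without WT head replicate 1) to 0.218 with libraries left out. Lists called by camera numbered 4 in the heads, 4 in the epiblast and 5 for the interaction. With an estimated correlation 0, 0 and 0 were called, 0 also at an unadjusted p under 0.05 in each, and by fry 0, 7 and 8. Leave-outs gave 2 to 6 lists in the heads, with 2 without either DKO epiblast, WT head replicate 2 or DKO head replicate 1, and 3 to 5 and 5 to 7 for the others. The cause of these was not tested.

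Mean methylation of E8.5 KO minus WT heads moved from 0.0204 points to −0.129 with at least 3 reads and 0.144 with at least 10, against an interval half-width of 0.0730. That of the KO head minus epiblast turned from −0.627 to 1.30 with at least 3 reads and was −0.775 with at least 10. CpG-dense regions differing in the heads numbered 116, and 357 and 4 with at least 3 and 10 reads, 401 and 40 with differences of 0.1 and 0.3, 283 and 43 with at least 5 and 20 shared CpGs, and 467 from summed reads. Between KO stages 98 became 554, 2, 408, 32, 313, 15 and 877 in the same order. Bins in the heads numbered 150, and 1432 and 1, 1079 and 30, and 1031 and 31 under the same choices, and 49 at 100 kb. Between KO stages 133 bins became 2572, 1, 576, 38, 738 and 16. Lower minimums admit more regions with fewer reads by construction, and the cause of the turned mean was not tested. Of 10 named regions, with at least 3 reads 4 stayed, 5 moved and 1 reversed (chromosome 10 from 80933318, 1.72 points). From summed reads 2 stayed, 7 moved and 1 reversed (chromosome X from 147481064, 0.401). A minimum of 5 shared CpGs or leaving out CpGs over 100 reads left every value identical, so these settings test nothing for these regions.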

Other observations

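Of the tests in this part, the Hox gene share in E8.5 heads, the clustering of genes that differ alike in both mutants and the sex test of those genes were chosen only after the results were seen.

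In the E6.5 Kmt2b KO epiblast, several lists stayed close to WT. Medians were 0.10 for Polycomb genes (percentile 95.5), 0.13 for DNA methylation genes (94.1), 0.20 for immediate early genes (95.9), −0.13 for germline genes (9.80) and −0.20 for visceral endoderm (9.48). In E8.5 KO heads the glucose transporter gene Slc2a3 differed by 1.21 within a hypoxia and glycolysis median of 0.16 (percentile 98.4), and Chac1 by 1.08 within an amino acid stress median of 0.30 (percentile 99.7). Imprinted genes went both ways, with Peg12 (36.6 to 10.9 FPKM, −1.66), Mest (1380 to 546, −1.34) and Peg13 (−1.29) lower and Phlda2 (1.31) and Meg3 (1.25) higher, and a median of −0.12 (percentile 7.93). In the E9.5 KO library, p53 targets had a median of 0.48 with 3 of 16 at least 2-fold higher and 3 lower, such as Bax (1.64) and Perp (−2.43). Visceral endoderm had a median of 0.86 there, brain patterning 0.35 and the neural crest list −0.12, within which the mesenchymal genes Foxc1 (−1.86) and Prrx1 (−1.64) were lower. Between WT heads of E9.5 and E8.5 the medians were 1.86 for blood, 0.93 for ribosomal proteins, 0.33 for Polycomb genes, −0.54 for endothelium, −0.57 for immediate early genes and −0.42 for formative pluripotency.

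In the Tet1/2 DKO epiblast, 10 of 30 cell cycle genes rose and 4 fell at an adjusted p under 0.05 over all genes (limma), led by the replication gene Mcm2 (0.85), and 12 and 5 did so when adjusted over the list alone. Of p53 targets 8 of 18 rose and 1 fell, with Bbc3, an apoptosis gene, up by 1.71, of germline genes 7 of 16 rose and 1 fell, of hypoxia genes 11 of 25 rose and 3 fell, and of imprinted genes 3 of 27 rose and 5 fell. Of 6 visceral endoderm genes 2 rose, Spink3 and Cited1 (1.79). These lists had preset-correlation adjusted p of 0.22 to 0.51 by camera, and by fry the cell cycle list passed (adjusted p = 0.0037) and the others had 0.0525 to 0.0853. Over all genes 2260 of 11264 rose and 1710 fell, and fry does not set a list against the other genes. The counts are therefore not shown to be particular to these lists. Summed histone FPKM was higher in the DKO epiblast for each family tested, by 1.71 on the log2 scale for all 63 genes. In DKO heads 4 of 30 cell cycle genes were higher and 8 lower when adjusted over the list alone, and of 17 neural crest genes 3 were higher and 1 lower.

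The E8.5 Kmt2b KO heads may keep part of an earlier profile. Their difference from WT had a slope of 0.236 (Pearson's r 0.389 across genes) on the WT epiblast minus head difference of the other table, where 0 or less would have spoken against it. Of 181 epiblast-high genes 146 were higher in KO (80.7%) and of 186 head-high genes 121 were lower (65.1%), and without the pluripotency and streak lists the slope was 0.239. Tet1/2 DKO heads had a slope of 0.0354, with 48.4% of epiblast-high genes higher. A younger age of the KO embryos would give the same pattern and was not tested, and more posterior tissue in the KO heads stays open too, since 100% of the 4 Hox genes measured were higher.

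With histone and sex-linked genes left out, 42 genes differed at least 2-fold in the same direction in both E8.5 mutants, 25 higher, such as Hdac1 and Nptx2, and 17 lower, such as Hopx, Csrp1 and Pttg1. They may reflect sequence variants that the mutant strains share and that the WT lack. For variants acting in every tissue the bound set to speak against them, under 60%, was met. In the Tet1/2 DKO epiblast 15 of the 42 (35.7%) differed in that direction. But this counts signs whatever the size, such as −0.019 for 5730507C01Rik, and the WT epiblasts came from the other set. It therefore does not exclude such variants. Linked variants stay open, with 12 of 41 placed genes within 50 genes of another, against a mean of 3.81 and a highest value of 13 in 1000 random sets. Sex stays open as well, for the genes higher in both had a median of −0.0204 in the Y-high minus the Y-low DKO epiblast, 1 library each. No biological explanation was tested.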
